A study of Mus musculus with 10 samples.

How the data were processed

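Promoter-capture Hi-C was measured in 10 libraries from C57BL/6 mice. Promoter-capture Hi-C joins fragments of crosslinked chromatin that lay near each other in the nucleus, and then pulls down the joined fragments that hold a promoter. The libraries form 5 groups of 2 biological replicates: wild-type (WT), Npm1c, Flt3-ITD and double-mutant (DM, Npm1c with Flt3-ITD) haematopoietic stem and progenitor cells (HSPCs), and WT neutrophils. Per the labels, the HSPCs were the lineage-negative fraction of bone marrow from a depletion kit, and the neutrophils came from an isolation kit. Per the labels' protocols, the cells were fixed in 1% formaldehyde for 10 minutes, the chromatin was digested with HindIII, and 39,684 probes captured the fragments of 22,047 promoters.

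Per the labels, the genome build was mm10. The aligner, the interaction caller and its filters were not given in the sources used here. Each deposited file lists pairs of a captured promoter fragment (the bait) and another HindIII fragment, with 1 score per library. The deposited score is an interaction score that is never negative; it is neither a read count nor a ratio, and what it is relative to is not stated. Per the file headers, a further column gives another quantity, the distance in bp from the bait to the other end, and it is empty for pairs on different chromosomes. The 8 HSPC libraries list the same 88,624 pairs, and each pair scores at least 5 in both replicates of at least 1 HSPC group. The neutrophil libraries list 25,622 pairs, all at 5 or more in both replicates, and 14,093 pairs are in both lists. The files hold no counts, so the depth of each library is unknown, no counting interval can be given, and only the spread between replicates limits the precision.

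Before the data were examined, the files were taken to hold compartment scores of genomic bins, and the comparisons, contrasts, gene lists, thresholds and most alternatives were fixed on that assumption. The scores proved to belong to fragment pairs, so each planned test of bins was run on pairs, as log2 of the score plus 1. The tests that need a signed compartment score (larger bins, turning of signs, the share of bins in the A compartment, switches of sign) were replaced by the share of pairs at 5 or more and by counts of pairs gained and lost at 5. The tests per promoter were chosen after the data had been seen, because pairs enter the list only when a group scores 5 or more, which inflates differences between the group that passed and a group that did not.

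Pairs were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes, two-sided, Benjamini-Hochberg at 0.05) over the 88,421 pairs on autosomes and X; the 203 pairs on Y or unplaced sequence were left out. The 8 HSPC libraries shared 1 fit, and the neutrophil comparison used the 4 WT libraries and the 14,051 shared pairs. The contrasts were Npm1c, Flt3-ITD and DM against WT, DM against each single mutant, the interaction (DM minus Npm1c minus Flt3-ITD plus WT, which asks whether the double mutant departs from the sum of the single mutants) and WT neutrophils against WT HSPCs. Promoters were tested on the mean of log2 of the score plus 1 over the pairs of a bait, for baits with at least 10 such pairs, in the libraries compared. Only pairs that a group outside the comparison had brought into the list were used, so that the selection did not use the scores of the groups compared. These outside groups are not neutral: for each mutant against WT they were mutants too, which can favour pairs higher in mutants. For the interaction no group lies outside, so all listed pairs were used, and the selection was not removed. For neutrophils against WT HSPCs the pairs at 5 or more in both cell types were used.

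Genes were assigned to a bait when the start or end of a protein-coding gene in the GRCm38.p6 gene table lay in the fragment. The table gives no strand, so either end counts. This gave 11,505 genes a bait, 1,154 of them (10.0%) in 2 baits, and a mean per bait is given wherever a gene has more than 1. Npm1, Hoxa9, Kit, Cd34, Hoxb4, Gfi1 and Pbx3 had no bait among the listed pairs and could not be measured. Only baits with a listed pair are known here, so their promoters may have been captured without a listed contact.

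The 17 gene lists, fixed before the data were examined, hold the HoxA and HoxB cluster with Meis1 and Pbx3, stem and progenitor genes, Flt3-ITD and STAT5 response genes, early granulocyte and monocyte progenitor genes, mature neutrophil genes, erythroid genes, megakaryocyte and platelet genes, B lineage genes, T and NK lineage genes, macrophage and dendritic genes, basophil, eosinophil and mast cell genes, interferon response genes, cell cycle genes, leukaemia suppressor and differentiation factors, adhesion and marrow stroma genes, neural genes held as a silent reference, and housekeeping genes. Each list was compared with all other gene-bearing baits by limma's camera with a preset correlation of 0.01 on the mean over all listed pairs of a bait, with Benjamini-Hochberg adjustment over 116 list tests. Single members were tested over all promoters with at least 1 pair, and again adjusted over the list alone.

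Named pairs follow the rule fixed beforehand: up to 10 regions of called pairs per direction and contrast by the size of their mean difference, regions of a single pair last, without predicted genes. Named promoters follow a rule chosen after the data had been seen: those called with the deposited scores and with quantile normalization, up to 10 per direction with a gene symbol, largest difference first. Npm1, Flt3, Hoxa9, Meis1, Gata1, Cebpa, Elane and Ly6g were fixed beforehand as genes to give in every contrast. Some items that these rules select are withheld and are not reported here. Any other gene named was chosen after its values were seen.

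The share of pairs at 5 or more was compared between groups with the exact permutation test, two-sided. Differences per promoter are given with their standard error from limma (SE), and group values with the standard deviation (SD), both with 2 libraries per group. In limma this SE is drawn towards a spread shared by all promoters. The pipeline was tested on simulated data in which 200 of 1,841 promoters were shifted in DM HSPCs, and the promoters of the erythroid list were lowered by 0.5 as well. Of the 200, 73% of those shifted by 0.5 and 99% of those shifted by 1 on the log2 scale were recovered, none in the wrong direction. Another 9 promoters were called, which can include lowered erythroid ones. Noise was drawn for each pair alone, so variation shared by the pairs of a promoter was not simulated. With no simulated difference between groups, 8.92% of the pairs that had passed a selection like that of the files had an unadjusted p under 0.05, against 4.94% of the pairs selected by other groups. After adjustment 0 were called in either set.

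The alternatives were other scalings (quantile normalization; median centred and SD scaled), asinh or no transformation, other thresholds, other minimums of pairs per promoter, pairs with no score of exactly 0, only the groups compared or all libraries in the fit, autosomes only, Y and unplaced sequence kept, baits with a protein-coding gene end, eBayes with trend and robust, the replicate number as a block, fry and an estimated correlation for the lists, and each library left out. Tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9.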

Results

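Promoter contacts were scored in 8 lineage-negative bone marrow libraries, from WT, Npm1c, Flt3-ITD and DM mice, and in 2 WT neutrophil libraries. Npm1c is a leukaemia mutation that moves nucleophosmin to the cytoplasm, and Flt3-ITD is an internal duplication that keeps the cytokine receptor Flt3 active. The HSPC list held 88,624 pairs on 12,186 baits, and the neutrophil list held 25,622. Pairs at 5 or more in both replicates numbered 30,921 in WT, 37,062 in Npm1c, 45,413 in Flt3-ITD and 43,228 in DM HSPCs. The median distance to the other end was 183 kb for WT, 200 kb for Npm1c, 205 kb for Flt3-ITD, 204 kb for DM and 160 kb for neutrophil pairs.

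Over the listed pairs, which were selected for a high score in both replicates of a group, replicates resembled each other more than libraries of different groups did. Over all listed HSPC pairs the Spearman correlation was 0.481 to 0.547 within groups and 0.127 to 0.422 between groups. Between groups its mean was lowest for DM with Npm1c (0.183) and DM with WT (0.187), and highest for Npm1c with Flt3-ITD (0.363). Of the pairs, 56.3% reached 5 in both replicates of 1 HSPC group only and 10.2% in all 4 groups. Over the pairs at 5 or more in all 4 groups the Spearman ranges overlapped, with 0.412 to 0.597 within and 0.263 to 0.621 between groups. The list itself favours such differences, because a pair enters through the group that passed.

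The mutants carried more pairs at 5 or more than WT HSPCs, and the increase was not resolved by a test with 2 libraries per group. The mean share was 50.2% (SD 4.56) in WT, 56.7% (SD 6.84) in Npm1c, 64.1% (SD 0.0335) in Flt3-ITD and 61.3% (SD 0.724) in DM HSPCs. The differences from WT were 6.47, 13.9 and 11.1 percentage points (exact permutation p = 0.667, 0.333 and 0.333, where 0.333 is the smallest possible). For Npm1c the difference was 11.3 without Npm1c replicate 1, 1.63 without Npm1c replicate 2, 9.69 without WT replicate 1 and 3.24 without WT replicate 2. DM differed from Npm1c by 4.62 points (p = 0.667) and from Flt3-ITD by -2.82 points (p = 0.333) in the same exact test.

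**Figure D1:**
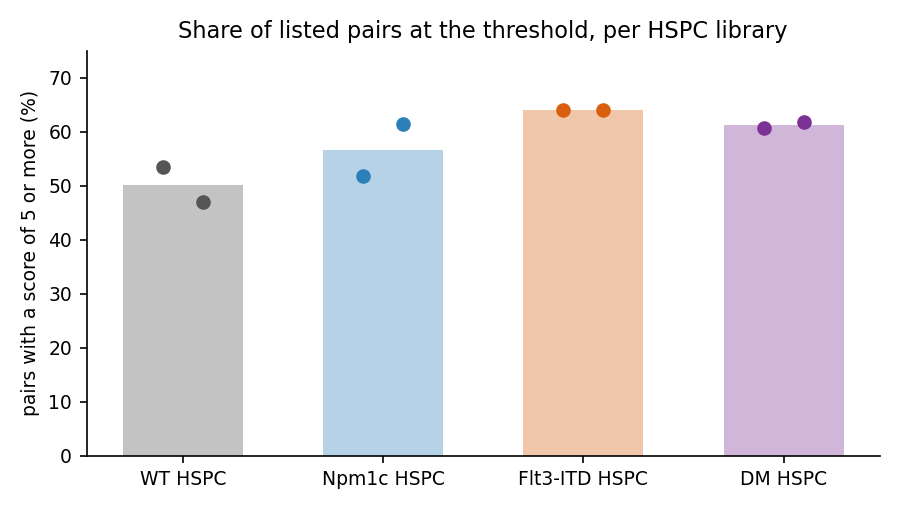
Percent of the listed HSPC pairs with a score of at least 5, with bars at the group mean and dots for libraries. The means were 50.2% in WT, 56.7% in Npm1c, 64.1% in Flt3-ITD and 61.3% in DM HSPCs.

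Npm1c HSPCs differed from WT HSPCs at few promoters. The promoters with stronger contacts were those of Mad2l1, a component of the spindle checkpoint, Fat4, an atypical cadherin, and Plk2, a kinase of the cell cycle and the stress response. Mad2l1 contacted fragments on another chromosome in the Npm1c libraries. Contacts between the region of Kif11, a mitotic motor, and that of Fgfbp3, a carrier of fibroblast growth factors, were strong in WT HSPCs and WT neutrophils. They were weak in every mutant HSPC group and so are not particular to Npm1c.

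Of 1,960 promoters tested in Npm1c against WT HSPCs, 3 were higher and 0 lower (limma, 103 at an unadjusted p under 0.05). The difference was 3.47 log2 units (SE 0.44, adjusted p = 8.54e-06) at Mad2l1 (6:66534905-66540307), 1.44 (SE 0.26, adjusted p = 0.0032) at Fat4 and 1.17 (SE 0.25, adjusted p = 0.031) at Plk2. With quantile normalization 0 promoters were called (100 unadjusted), and 0 with at least 1, 3 or 5 pairs per promoter (637, 371 and 235), so none meets the rule for named promoters, and these 3 are given because they are all the calls. Without WT replicate 1 or WT replicate 2 the count was 2, without Npm1c replicate 1 it was 1 and without Npm1c replicate 2 it was 4. The median over all tested promoters was shifted by 0.15.

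Of 88,421 single pairs, 199 scored higher and 75 lower in Npm1c HSPCs (11,027 unadjusted). Mad2l1 with 11:46622012-46624447 scored 33.7 (SD 2.14) in Npm1c and 2.03 (SD 2.87) in DM HSPCs and was listed at 0 in WT and Flt3-ITD HSPCs. Kif11 (19:37376212-37377006) with a fragment 462 kb away beside Fgfbp3 scored 29.0 (SD 7.89) in WT, 0.201 (SD 0.284) in Npm1c, 0.0662 (SD 0.0936) in Flt3-ITD and 1.49 (SD 2.11) in DM HSPCs (Npm1c minus WT -4.64, SE 0.60, adjusted p = 0.0274). From the other side, the Fgfbp3 bait (19:36916623-36921054) with a fragment beside Kif11 scored 26.2 (SD 5.77), 0.551 (SD 0.780), 2.61 (SD 1.27) and 4.90 (SD 0.590) in the same order. WT neutrophils scored 13.9 (SD 8.60) at the Kif11 pair and 18.1 (SD 1.32) at the Fgfbp3 pair. Both pairs were thus high in both WT cell types and lower in every mutant group. Whether a mutation or another difference between WT and mutant mice lies behind this was not tested. Pair calls were also lower at Tcea1, a transcription elongation factor, and Mcm3, a subunit of the replicative helicase; their shared other end, 1:88276241-88278577, was listed at 0 in every mutant HSPC library.

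The pair calls of Npm1c against WT depended on every library: 0 were made without WT replicate 1 (11,824 unadjusted), WT replicate 2 (9,881), Npm1c replicate 1 (8,364) or Npm1c replicate 2 (11,241). Among the pairs that Flt3-ITD or DM HSPCs had brought into the list, 0 were called (5,900 unadjusted). Such pairs went from under 5 to at least 5 in 3,389 cases and the other way in 1,581, a total of 4,970, against 3,993 and 4,868 for the other 2 ways to split these 4 libraries into groups.

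Flt3-ITD HSPCs had stronger contacts than WT HSPCs at the promoter of Myc, a driver of growth and proliferation that lies in a broad desert holding distant blood enhancers. Contacts were also stronger at Tnfrsf21, a death receptor, at Styk1, a receptor-like kinase, and at the linker histone gene H1f3. With the deposited scores alone, Cish, a feedback inhibitor induced by STAT5, the early response genes Egr3 and Fos, the lymphoid factor Ikzf1 and the progenitor factor Sox4 were higher as well. They are single promoters picked from many, and the list of Flt3-ITD and STAT5 response genes did not pass its test.

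Of 1,858 promoters tested in Flt3-ITD against WT HSPCs, 143 were higher and 0 lower (567 unadjusted), and the median promoter was shifted by 0.28, to 0.01 with quantile normalization. Quantile normalization called 13 higher and 4 lower, and 13 were called both ways. Of these, 9 carry a gene symbol: Mad2l1 (2.06, SE 0.33), Myc (1.54, SE 0.22, adjusted p = 2.56e-05), Styk1 (1.24, SE 0.22), Tnfrsf21 (1.17, SE 0.20), Ttc33 (1.14, SE 0.22), Cln8 (1.13, SE 0.21), Fat4 (1.11, SE 0.20), Usp38 (1.11, SE 0.21) and H1f3 (1.08, SE 0.20). Myc (15:61984173-61985527, 21 pairs) kept its call with each of the 4 libraries left out and lost it when promoters with at least 1 or 3 pairs were tested (adjusted p = 0.44 and 0.127), and its mean was higher in both Flt3-ITD than in both WT libraries. With the replicate number as a block, limma called 0 promoters in this contrast, so the Myc call was lost there too. The pairs of Myc at 5 or more in both replicates numbered 2 in WT, 8 in Npm1c, 18 in Flt3-ITD and 16 in DM HSPCs.

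Calls with the deposited scores alone, chosen here after their values were seen, were Egr3 (0.94, SE 0.21, 0.62 after quantile normalization), Cish (0.87, SE 0.19, 0.64 after it), Sox4 (0.84, SE 0.20), Ikzf1 (0.76, SE 0.19) and Fos (0.76, SE 0.22). The count of Flt3-ITD promoter calls was 1 with at least 1 pair per promoter, 0 with at least 3 (1,022 unadjusted) and 38 with at least 5. It was 641 without WT replicate 1, 88 without WT replicate 2, 31 without Flt3-ITD replicate 1 and 7 without Flt3-ITD replicate 2. The adjusted p of Cish was 0.00594 with the deposited scores and 0.105 with quantile normalization.

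Of the 88,421 pairs, 422 scored higher and 80 lower in Flt3-ITD than in WT HSPCs (12,524 unadjusted), and 279 higher and 169 lower with quantile normalization. The higher pairs included contacts of Igfbp3, a carrier of insulin-like growth factors, Cd244a, a receptor of NK cells, Itln1 and Mptx1, an intelectin and a pentraxin of innate defence, and the splicing gene Sf3b5. Cd244a (1:171554067-171561635) with 14:90084435-90087987 scored 77.3 (SD 10.6) in Flt3-ITD and 5.13 (SD 0.0741) in Npm1c HSPCs and was listed at 0 in WT and DM HSPCs. The lower pairs again included Fgfbp3, Kif11, Tcea1 and Mcm3. The count was 3 without WT replicate 1, and 0 without WT replicate 2 (10,258 unadjusted), Flt3-ITD replicate 1 (8,047) or Flt3-ITD replicate 2 (8,445). Among pairs brought in by Npm1c or DM HSPCs 12 were called (7,096 unadjusted), and 4,845 of these pairs were gained at 5 and 1,139 lost (a total of 5,984, against 3,655 and 3,675 for the other ways to split the libraries).

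The DM HSPCs, which carry both mutations, changed in both directions. Contacts were stronger at Parp8, a member of the ADP-ribosyl transferase family, at Thbd, the thrombin receptor thrombomodulin, and at its neighbours Cd93, a surface marker of early myeloid cells, and Sstr4, a somatostatin receptor. They were also stronger at Ccnd1, the G1 cyclin, at Myc, at Dse, an enzyme of dermatan sulphate synthesis, at the fatty acid receptors Ffar1 and Ffar3 and at Lgmn, a lysosomal protease. Contacts were weaker at Slc40a1, the iron exporter ferroportin, at Angpt2, a ligand of the Tie2 receptor, at Hdac6, a cytoplasmic deacetylase, at Wapl, which releases cohesin from chromatin, and at the tRNA synthetase gene Gars.

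Of 1,841 promoters tested in DM against WT HSPCs, 90 were higher and 15 lower (429 unadjusted), with a median shift of 0.09 (-0.03 with quantile normalization). The calls end when promoters with fewer pairs are added: 0 with at least 1 pair (1,177 unadjusted), 0 with at least 3 (1,002) and 1 with at least 5. Quantile normalization called 40 higher and 33 lower, among them 40 of the 90 and all 15 of the lower promoters. The largest increases called both ways were at Parp8 (13:117023125-117026559, 1.39, SE 0.23, adjusted p = 0.00974), Olfr1076 (1.18, SE 0.19), Snx18 (1.17, SE 0.21), Dse (1.15, SE 0.20), Thbd (1.14, SE 0.22), Ffar1 (1.14, SE 0.19), Ffar3 (1.11, SE 0.19), Lgmn (1.09, SE 0.23), Dlg4 with Asgr1 on 1 bait (1.05) and Tnfrsf21 (1.04, SE 0.21). Below these in size were Ccnd1 (7:144932206-144940810, 1.02, SE 0.22, adjusted p = 0.0215), Sstr4 (1.01, SE 0.22), Myc (0.99, SE 0.21, adjusted p = 0.0215) and Cd93 (0.98, SE 0.20), singled out after their values were seen.

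The decreases in DM HSPCs were at Slc40a1 (1:45924504-45928090, -1.15, SE 0.18, adjusted p = 0.00974), Olfr639 (-1.15, SE 0.19), Gars (-0.94, SE 0.19), Hdac6 (-0.83, SE 0.23, adjusted p = 0.0496), Wapl (-0.79, SE 0.19), Angpt2 (8:18739887-18741842, -0.78, SE 0.18, adjusted p = 0.0267), Aasdhppt with Kbtbd3 (-0.75, SE 0.19), Olfr69 (-0.74, SE 0.20) and Pgpep1l (-0.69, SE 0.18). At Slc40a1 the mean went from 3.33 (SD 0.09) in WT to 2.18 (SD 0.02) in DM HSPCs, and at Parp8 from 2.13 (SD 0.53) to 3.52 (SD 0.09). The DM promoter count was 241 without WT replicate 1, 1 without WT replicate 2, and 0 without DM replicate 1 (208 unadjusted) or DM replicate 2 (163 unadjusted).

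**Figure D2:**
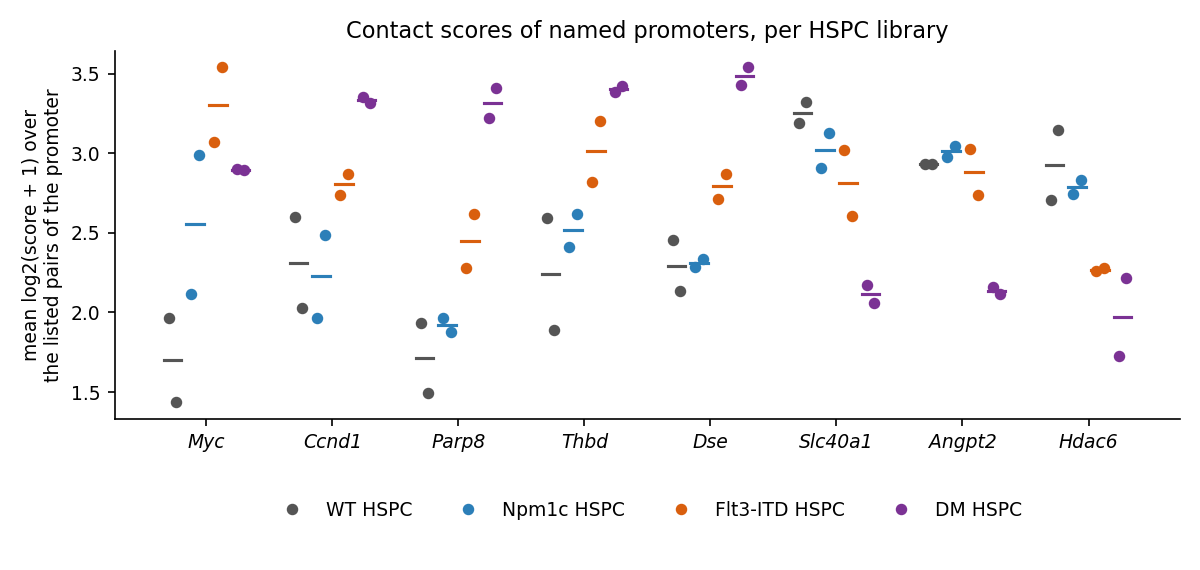
Mean log2 of the score plus 1 over all listed pairs of 8 promoters, with dots for libraries and lines at the group mean. Myc was 1.96 and 1.44 in the WT and 2.90 and 2.89 in the DM libraries, and Slc40a1 was 3.19 and 3.32 in the WT and 2.17 and 2.06 in the DM libraries.

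Of the 88,421 pairs, 371 scored higher and 138 lower in DM than in WT HSPCs (17,204 unadjusted), and 192 higher and 151 lower with quantile normalization. The promoter shared by Dhrs1, a dehydrogenase, and Nop9, a ribosome factor (14:55738899-55747349), with a fragment 90.1 kb away at Tssk4 scored 18.6 (SD 1.25) in DM HSPCs and 19.8 (SD 6.38) in WT neutrophils and was listed at 0 in the other HSPC groups. As an other end this Tssk4 fragment was at 0 for all its 5 pairs in WT, Npm1c and Flt3-ITD HSPCs, although as a bait it scored a mean of 3.96, 4.58 and 4.83 there, so the zeros need not be a loss of contact. Neu3, a sialidase of gangliosides (7:99824271-99830936), with a fragment 345 kb away scored 24.8 (SD 8.49) in WT, 40.7 (SD 7.04) in Npm1c and 34.5 (SD 2.43) in Flt3-ITD HSPCs and was listed at 0 in DM HSPCs. Other pairs were higher at Chordc1, Mcts1, Prickle1, Gdf2 and Fiz1, and lower at Tcea1, Mcm3, the histone genes of H4c8, Kif11 and the interferon-induced GTPase gene Igtp.

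The DM pair calls were 0 without WT replicate 1 (17,711 unadjusted), WT replicate 2 (12,701), DM replicate 1 (12,596) or DM replicate 2 (11,881). Among pairs brought in by Npm1c or Flt3-ITD HSPCs 1 was called (7,995 unadjusted), and 4,113 of these pairs were gained at 5 and 2,424 lost (a total of 6,537, against 3,698 and 3,714 for the other ways to split the libraries).

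Against the single mutants, DM HSPCs had stronger contacts at Dse and Ffar1 than Flt3-ITD HSPCs. They had weaker contacts at Vdac3, a channel of the outer mitochondrial membrane, at Uqcrh, a subunit of respiratory complex III, at Igfbp3, and at Herc1, a ubiquitin ligase. Against Npm1c HSPCs no promoter passed the test, while single pairs of Mad2l1 and of Rad51c, a gene of recombination repair, were weaker in DM HSPCs.

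Of 1,513 promoters tested in DM against Flt3-ITD HSPCs, 2 were higher and 88 lower (360 unadjusted), with a median shift of -0.16 (-0.10 over all listed pairs). Dse (0.64, SE 0.15, adjusted p = 0.025) and Ffar1 (0.56, SE 0.15, adjusted p = 0.0388) were higher, and 8 of the lower promoters were also called with quantile normalization. Among those were Vdac3 (8:22589865-22595364, -1.20, SE 0.21, adjusted p = 0.0087), Uqcrh with Lrrc41 (-1.0, SE 0.16), Igfbp3 (-0.98, SE 0.16), Olfr623 with Olfr624 (-0.97, SE 0.15) and Herc1 (-0.92, SE 0.17). The count was 1 with at least 1 pair per promoter, 0 with at least 3 (728 unadjusted) and 14 with at least 5. It was 71 without Flt3-ITD replicate 1, 34 without Flt3-ITD replicate 2, 22 without DM replicate 1 and 0 without DM replicate 2 (287 unadjusted). Against Npm1c HSPCs, limma called 0 of 1,729 promoters (271 unadjusted), and 6 higher and 5 lower with quantile normalization; the count was 90 without Npm1c replicate 1, 138 without Npm1c replicate 2, and 0 without DM replicate 1 (99 unadjusted) or DM replicate 2 (82 unadjusted).

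For single pairs, 246 scored higher and 250 lower in DM than in Npm1c HSPCs (15,633 unadjusted), and 121 higher and 284 lower than in Flt3-ITD HSPCs (10,577 unadjusted). Among the named pairs whose bait carries a gene symbol, Dhrs1 with Nop9 and Fiz1 with Zfp524 were higher against both, and Neu3 was lower against both. Mroh2a was lower against each at a different pair. Rad51c, Trappc12 and Mbnl2 were lower against Npm1c, and Cd244a, Itln1 and Mptx1 against Flt3-ITD HSPCs. Against Npm1c, 0 pairs were called without Npm1c replicate 1 (10,759 unadjusted), Npm1c replicate 2 (15,377), DM replicate 1 (11,577) or DM replicate 2 (10,833), and 1 among the pairs brought in by other groups (6,832). Against Flt3-ITD, 0 were called without Flt3-ITD replicate 1 (6,697), Flt3-ITD replicate 2 (7,830), DM replicate 1 (8,478) or DM replicate 2 (8,025), and 8 among the pairs brought in by other groups (4,546).

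Many promoters scored lower in the double mutant than the sum of the single mutants gives. At Vdac3, Rad51c with Tex14, the morphogen gene Shh and Igfbp3 the means were higher in each single mutant than in WT and DM HSPCs. A rise of the promoter mean over WT was called only for Vdac3 and Igfbp3, in Flt3-ITD HSPCs. None of these promoter means was called in Npm1c HSPCs, where a single pair of Rad51c with Tex14 was called higher than in WT. Fgfbp3 contacts were about as weak in each single mutant as in DM HSPCs. At Dhrs1 with Nop9 the mean of DM HSPCs was above those of the other HSPC groups, in which 1 of its partners, the Tssk4 fragment, was at 0 throughout.

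The interaction was tested at 2,833 promoters, where 8 were higher and 204 lower than the sum of the single mutants gives (702 unadjusted, median -0.21). Quantile normalization called 84 higher and 142 lower, and all 8 of the higher and 142 of the lower promoters were called both ways. The lower ones were led by Mad2l1 (-4.04, SE 0.81), Vdac3 (-2.18, SE 0.29, adjusted p = 0.0019), Arl4a (-2.17, SE 0.29), Rad51c with Tex14 (11:87389853-87406408, -2.06, SE 0.22, adjusted p = 0.00123), Olfr382 (-1.96, SE 0.27), Olfr685 (-1.96, SE 0.33), Shh (5:28463005-28467167, -1.92, SE 0.22, adjusted p = 0.00123), Igfbp3 (11:7212991-7216491, -1.91, SE 0.25), Zfp874a (-1.80, SE 0.37) and Zfp493 (-1.78, SE 0.31). The Shh mean was 1.79 (SD 0.05) in WT, 2.97 (SD 0.02) in Npm1c, 2.74 (SD 0.16) in Flt3-ITD and 1.99 (SD 0.05) in DM HSPCs. For Rad51c the means were 1.79 (SD 0.07), 2.62 (SD 0.03), 2.85 (SD 0.12) and 1.62 (SD 0.05).

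Higher in the interaction were Fgfbp3 (2.20, SE 0.26, adjusted p = 0.00123), Mtg1 with Sprn (1.11, SE 0.28), Gdf2 (1.09, SE 0.26), Dhrs1 with Nop9 (1.05, SE 0.25), Rab31 (1.03, SE 0.23) and Ccl6 (1.01, SE 0.27). The Fgfbp3 means were 3.36 (SD 0.18) in WT, 1.03 (SD 0.28) in Npm1c, 1.22 (SD 0.14) in Flt3-ITD and 1.08 (SD 0.09) in DM HSPCs; as scores cannot fall below 0, the low single mutants fix a positive interaction there, and it shows no departure in the double mutant. Vdac3, Arl4a, Rad51c, Olfr382, Shh, Igfbp3, Cmpk1 and Fgfbp3 were among the 15 promoters called with each of the 8 libraries left out. The count was 98 without WT replicate 2, 386 without Npm1c replicate 1, 128 without Npm1c replicate 2, 52 without Flt3-ITD replicate 1, 17 without Flt3-ITD replicate 2, 103 without DM replicate 1 and 39 without DM replicate 2. Here the pairs were selected by the groups compared, so pairs that entered through a single mutant give a negative interaction by selection alone, and pairs that entered through WT or DM HSPCs a positive one.

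Among single pairs the interaction was higher at 128 and lower at 371 (12,769 unadjusted). Lta4h, an enzyme of leukotriene synthesis (10:93450695-93457890), with 10:91159842-91175312 scored 9.99 (SD 3.91) in DM and 3.82 (SD 2.03) in WT HSPCs and was listed at 0 in both single mutants (interaction 5.61, SE 0.57). Here the zeros of the single mutants make most of the value. The calls at Kif11, Tcea1 and Fgfbp3 were fixed by single mutants near or at 0 and show no departure in DM HSPCs. Lower were Mad2l1, Btn1a1, Mbnl2, Mptx1, Cd244a and Rad51c. The count was 73 without Npm1c replicate 1, 4 without Npm1c replicate 2, 3 without Flt3-ITD replicate 2, 1 without WT replicate 1 or WT replicate 2, and 0 without Flt3-ITD replicate 1 (9,214 unadjusted), DM replicate 1 (10,937) or DM replicate 2 (10,638).

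Across gene lists, the promoters of erythroid genes as a group, a list of globin, red cell membrane and haem genes, had weaker contacts relative to other promoters in DM HSPCs than in WT and Npm1c HSPCs. Promoters of macrophage and dendritic genes as a group, with class II and phagocyte genes, had stronger contacts in DM than in Npm1c HSPCs. Both calls are lost when the correlation between genes is estimated from the data (adjusted p = 0.924 with an estimated correlation), and in none of the called lists did a single member pass. The HoxA and HoxB cluster with Meis1, the self-renewal programme of Npm1-mutant leukaemia, and mature neutrophil genes were higher in DM than in WT HSPCs without passing the adjusted test.

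In DM against WT HSPCs the 20 erythroid baits differed by -0.43 on average, -0.65 relative to other promoters (adjusted p = 0.00113, with 0.00389 after quantile normalization and 0.00107 for the pairs brought in by other groups with only the groups compared in the fit). Over the 18 baits with such pairs the median was -0.39 and the mean relative to other promoters -0.48, with 14 baits below 0. Against Npm1c HSPCs the erythroid list differed by -0.46 (-0.56 relative to others, adjusted p = 0.00762), and against Flt3-ITD HSPCs by -0.34 (adjusted p = 0.0734, and 0.0137 for pairs brought in by other groups with only the groups compared in the fit). The macrophage and dendritic list of 24 baits differed by 0.61 in DM against Npm1c HSPCs (0.51 relative to others, adjusted p = 0.00762, and 0.0725 for pairs brought in by other groups with only the groups compared in the fit). All 3 calls held with each library left out. None is called with an estimated correlation between genes (each with an adjusted p = 0.924 with an estimated correlation). Fry, which asks whether a list changed at all and not whether it differs from other promoters, gave 0.0622 for each.

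**Figure D3:**
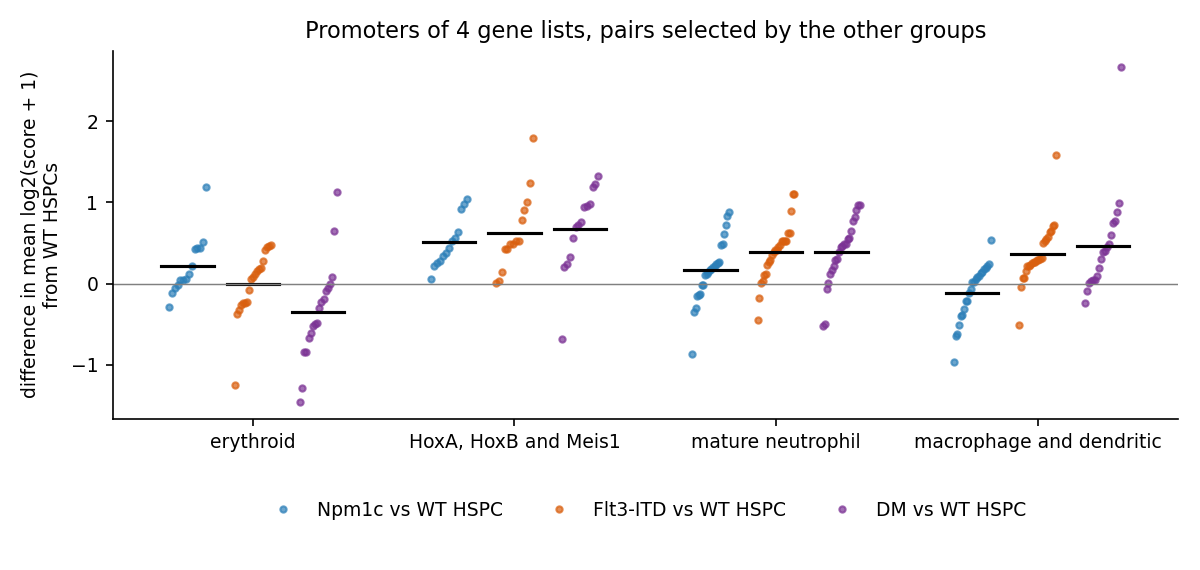
Difference from WT HSPCs per bait in each mutant for 4 gene lists, over pairs brought in by the other groups. In DM HSPCs 14 of 18 erythroid baits lay below 0, with a median of -0.39.

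The Hox list of 15 baits differed by 0.74 in DM (adjusted p = 0.0613, 0.0243 after quantile normalization, 0.0145 for pairs brought in by other groups with only the groups compared in the fit), 0.62 in Npm1c (adjusted p = 0.1) and 0.63 in Flt3-ITD HSPCs (adjusted p = 0.107), all against WT. Its HoxA and HoxB genes are clustered, so these baits are not independent, while the preset correlation of 0.01 treats them nearly so. No single locus was left out for this list. Mature neutrophil genes differed by 0.59 in DM HSPCs over 26 baits (adjusted p = 0.0623, 0.0117 with fry). With an estimated correlation between genes, camera called 0 lists in DM against WT HSPCs. No list was called in Npm1c against WT (2 of 17 unadjusted with limma's camera), Flt3-ITD against WT (4), DM against Flt3-ITD (3), the interaction (2) or the neutrophil comparison (0 of 14). The smallest adjusted p of each remaining list was 0.179 for Flt3-ITD and STAT5 response genes (0.50), leukaemia suppressor and differentiation factors (0.56) and early granulocyte and monocyte progenitor genes (0.58), 0.251 for B lineage genes (0.51) and 0.711 for adhesion and marrow stroma genes (0.51), all in DM against WT. It was 0.251 for housekeeping genes in Npm1c against WT (-0.18 relative to others). In the interaction it was 0.1 for the neural reference (-2.67 over 3 baits), 0.300 for stem and progenitor genes (-0.26), 0.410 for T and NK lineage genes (0.14 relative to others) and 0.497 for interferon response genes (0.07). It was 0.488 for megakaryocyte and platelet genes in neutrophils (0.53), and, in DM against Flt3-ITD, 0.556 for basophil, eosinophil and mast cell genes (0.27) and 0.594 for cell cycle genes (-0.09).

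Of the 17 erythroid genes in DM against WT, 0 passed over all promoters and 0 when adjusted over the list alone (limma, 3 lower unadjusted: Hbb-bt -1.46, SE 0.31, Rhag -0.84, SE 0.24, and Car1 -0.61, SE 0.18). Against Npm1c 0 passed either way (6 lower unadjusted, among them Rhag -0.89, SE 0.21), as 0 of the macrophage and dendritic genes did (2 higher unadjusted, among them Mertk 0.98, SE 0.22), and against Flt3-ITD 0 either way (4 lower unadjusted, among them Car1 -0.88, SE 0.20). In DM against WT the Hox list had 0 and 0 (4 higher unadjusted, among them Meis1 1.32, SE 0.33, and Hoxa10 with Hoxa11 1.23, SE 0.23), the mature neutrophil list 0 and 0 (3 higher unadjusted, among them Mmp8 0.82, SE 0.18), and the macrophage and dendritic list 0 over all and 1 over the list alone (Siglech 2.66, SE 0.33). In the stroma list 1 passed over the list alone (Runx2 2.38, SE 0.29). In the STAT5 list of Flt3-ITD against WT 0 and 0 passed (5 unadjusted, among them Socs2 1.02, SE 0.22). In the interaction, Cdc20, an activator of the anaphase complex (-3.26, SE 0.23, adjusted p = 0.00355), the T lineage factor Tcf7 (1.61, SE 0.29, adjusted p = 0.0488) and Grin2a of the neural reference (-5.20, SE 0.93, adjusted p = 0.0481) passed over all promoters, and among others Sox4 (-1.33, SE 0.28) and Mycn (-1.23, SE 0.31) passed over the list alone. Members of the neural reference passed over the list alone at 2 of 2 baits in Flt3-ITD against WT (higher) and 2 of 3 in the interaction (lower). They also passed at 1 of 2 in DM against Npm1c (lower) and 1 of 1 in neutrophils (higher).

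Of the genes fixed beforehand, Gata1, the master factor of red cells, had 5 pairs at 5 or more in both WT replicates, 1 in Npm1c and 0 in Flt3-ITD and DM HSPCs and in neutrophils. Cebpa, the master factor of granulocytes, had 0 in WT and Npm1c, 1 in Flt3-ITD, 6 in DM HSPCs and 1 in neutrophils. None passed a test in any contrast, and contrasts without a value had no pair to test.

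The values below run over Npm1c, Flt3-ITD and DM against WT, DM against Npm1c, DM against Flt3-ITD and the interaction. Meis1 differed by 0.98 (SE 0.35), 1.24 (SE 0.34), 1.32 (SE 0.33), 0.44 (SE 0.21), 0.30 (SE 0.27) and -0.59 (SE 0.40). Ly6g differed by 0.83 (SE 0.40), 1.10 (SE 0.37), 0.91 (SE 0.34), -0.29 (SE 0.30), -0.30 (SE 0.30) and -0.52 (SE 0.53). Elane differed by -0.02 (SE 0.22), 0.03 (SE 0.20), 0.05 (SE 0.20), 0.16 (SE 0.23), -0.02 (SE 0.21) and 0.06 (SE 0.27) on the bait at its start, and by 0.36 (SE 0.28), 0.33 (SE 0.24), 0.02 (SE 0.22), -0.44 (SE 0.21), -0.35 (SE 0.19) and -0.48 (SE 0.28) on the other. Cebpa, with no value against Flt3-ITD, differed by 0.13 (SE 0.30), 0.60 (SE 0.26), 1.31 (SE 0.38), 1.01 (SE 0.37) and 0.52 (SE 0.36). Gata1, with no value in Npm1c against WT, differed by -1.25 (SE 0.48), -1.28 (SE 0.50), -0.68 (SE 0.26), -0.49 (SE 0.18) and 0.18 (SE 0.32). Flt3 differed on one bait by -0.39 (SE 0.29), 1.58 (SE 0.35, unadjusted p = 0.00809), 0.39 (SE 0.30), 0.79 (SE 0.30) and, in the interaction, -0.28 (SE 0.38). On its other bait it differed from WT by -0.12 (SE 0.24), -0.05 (SE 0.29) and 0.45 (SE 0.60), in DM against Flt3-ITD by 0.19 (SE 0.73) and in the interaction by 0.80 (SE 0.39). In neutrophils against WT HSPCs only Elane had a value (-0.25, SE 0.21). Npm1 and Hoxa9 have no bait among the listed pairs. Only 1 pair lay behind each of the Flt3 values 1.58, 0.45 and 0.19, the Gata1 values -1.25 and -1.28 and the Cebpa values 1.31 and 1.01.

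WT neutrophils, compared with WT HSPCs, had many more contacts at some promoters and far fewer at others. Retnlg, an abundant secreted protein of neutrophils, Selp, an adhesion receptor that slows rolling cells, and Cxcr4, the receptor that holds neutrophils in marrow, were among the former, as were Parp8, Klhl2, B4galt6, Rwdd2b, Dock5, an activator of Rac in migrating cells, and Thbd. Most HSPC contacts were missing from neutrophils at the promoters of Ikzf2, a factor of lymphoid and stem cells, Angpt2, Rrm2, which makes nucleotides for replication, and the mRNA cleavage gene Cpsf3.

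Pairs at 5 or more in both replicates, with the number in DM HSPCs in brackets, went from 1 in WT HSPCs to 55 in neutrophils at Parp8 (82), 2 to 54 at Klhl2 (7), 0 to 51 at B4galt6 (5), 4 to 47 at Dock5 (2), 4 to 44 at Thbd (45), 20 to 57 at Ptpre (20), 0 to 36 at Selp (0), 10 to 44 at Rwdd2b (4) and 3 to 36 at Sstr4 (33). They went from 76 to 0 at Cpsf3 with Iah1 (57), 47 to 0 at Pqbp1 with Timm17b (13), 46 to 1 at Ikzf2 (13), 55 to 11 at Angpt2 (4), 55 to 12 at Mapk12 with Mapk11 (60), 44 to 3 at Armc5 with Tgfb1i1 (16), 42 to 4 at Styk1 (57), 42 to 7 at Net1 (38), 40 to 5 at Plxnb2 with Dennd6b (22) and 38 to 3 at Rrm2 (20). Retnlg had 22 in neutrophils and 0 in every HSPC group, and Cxcr4 had 10 in WT HSPCs and 36 in neutrophils. These counts carry no test, since the 2 files list different pairs, and 7,936 pairs were shared between WT HSPCs and neutrophils (31.0% of the neutrophil pairs).

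**Figure D4:**
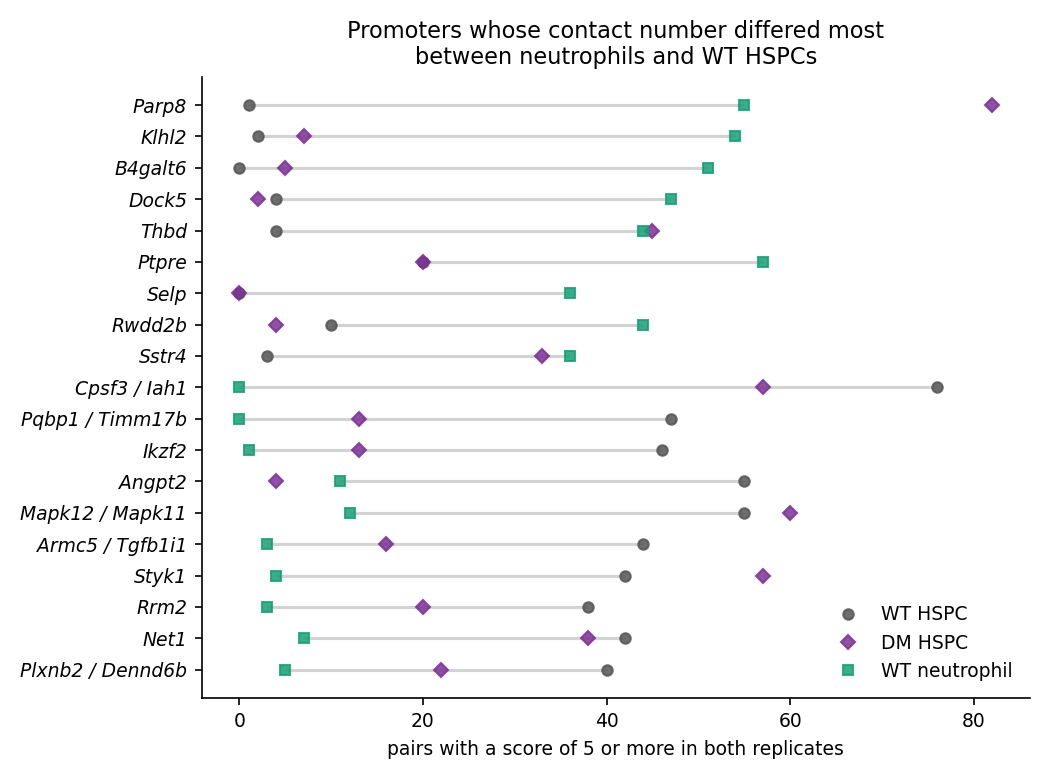
Number of pairs at 5 or more in both replicates of WT HSPCs, DM HSPCs and WT neutrophils for 19 promoters. Parp8 had 1, 82 and 55, and Angpt2 had 55, 4 and 11.

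The mature neutrophil list held 144 pairs in neutrophils and 75 in WT HSPCs, at percentile 99.8 of random sets of promoters, with 14 of 24 baits having more in neutrophils. The erythroid list held 46 and 105 (percentile 0.56, with 15 of 17 baits having more in WT HSPCs), the stem and progenitor list 14 and 44 (percentile 1.02) and the megakaryocyte and platelet list 104 and 36 (percentile 99.8, with 8 of 13 baits having more in neutrophils). Of those 104 pairs, Selp alone held 36 on one of its baits and 18 on the other. These percentiles are not adjusted over the lists.

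Among pairs in both files, 29 of 14,051 scored higher in neutrophils and 0 lower (2,803 unadjusted, median shift 0.30), and limma called 0 with quantile normalization (2,013 unadjusted), 0 of the pairs with no exact 0 (2,836) and 0 of the pairs at 5 or more in both cell types (1,004). They included Dhrs1 with Nop9, the cannabinoid receptor gene Cnr2, the transglutaminase gene Tgm1 and histone genes such as H4c9; Dhrs1 and Tgm1 were paired with the Tssk4 fragment that was at 0 throughout in WT HSPCs. Of 112 promoters with at least 10 pairs at 5 or more in both cell types, 14 were higher and 2 lower (29 unadjusted, median shift 0.08). With quantile normalization 15 were higher and 8 lower, with at least 3 pairs 16 and 13, and with at least 1 pair 1 and 2. With the replicate number as a block 0 were called. Higher were Slc35f5 (0.98, SE 0.16, adjusted p = 3.43e-07), Uba6 (0.83), Slc40a1 (0.76), the phosphatase gene Ptpre (0.63), Cdkn2aipnl (0.61), Trappc12 (0.57), Irf2bp2 (0.56), Ccdc83 (0.50), Tspan14 (0.45) and the myeloid factor gene Mzf1 (0.45), and lower was Farsa (-0.49). The SE was 0.16 at every called promoter, because limma pooled 1 spread over all promoters tested. These adjusted p values therefore do not reflect the spread of each promoter between its own libraries. The pair count was 623 without WT HSPC replicate 1, 75 without WT HSPC replicate 2 and 0 without neutrophil replicate 1 (1,306 unadjusted) or neutrophil replicate 2 (1,231). The promoter count was 6 without WT HSPC replicate 2, 3 without neutrophil replicate 1 and 7 without neutrophil replicate 2.

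Along the difference between WT HSPCs and neutrophils, the mean over pairs, counted positive towards neutrophils, was 0.06 in Npm1c, 0.17 in Flt3-ITD and 0.22 in DM HSPCs, and 0.04, 0.07 and 0.14 after quantile normalization. With the deposited scores it came from the more numerous pairs higher in neutrophils (0.11, 0.30 and 0.31), while pairs lower in neutrophils were also above WT (0.06, 0.17 and 0.01); after quantile normalization these were at -0.03, -0.05 and -0.12. This mean covers pairs that differed between neutrophils and a WT HSPC library, and the mutants were compared with the other WT HSPC library, both ways round. With the deposited scores it ran from -0.06 to 0.15 in Npm1c, 0.14 to 0.21 in Flt3-ITD and 0.17 to 0.26 in DM HSPCs over libraries and WT splits. The listed pairs were still selected by the scores of the HSPC groups, so a shift without any biology is not excluded.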

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

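The tests in this part were chosen only after the result was seen, except the interaction over pairs and the test with single chromosomes left out of the erythroid list. The difference between the double mutant and the sum of the single mutants was tested as an interaction, and it passed at 499 pairs and 212 promoters. At Shh, Rad51c, Vdac3 and Igfbp3 the promoter means were higher in each single mutant than in WT and DM HSPCs. A rise of these means over WT was called only for Vdac3 and Igfbp3, and only in Flt3-ITD HSPCs. The pairs behind the interaction were listed because at least 1 of the 4 groups passed 5, so the count holds an unknown share due to that selection.

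Signal was also present in data that the comparisons did not use: the 203 pairs on Y or unplaced sequence. Their median score was 20.3 in Npm1c replicate 2 and 13.7 and 17.6 in Flt3-ITD replicates 1 and 2, above the WT medians of 7.38 and 6.23; it was 7.75 in Npm1c replicate 1 and 6.76 and 5.43 in the DM libraries. The labels give no sex for the mice, and no explanation was tested.

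The calls of single pairs between HSPC groups were weighed against the construction of the list. The call rate among pairs that an outside group had brought in was 0.123 times the rate among the other pairs (0.152% against 1.24%). This ratio cannot separate selection from true differences, since a true contact of 1 compared group also enters the list only through that group. With no simulated difference and 1 spread for all pairs, limma called 0 of 36,709 pairs that had passed a selection like that of the files. Over the 80,673 pairs with no exact 0 in any HSPC library, limma called 0 in each comparison of HSPC groups (9,280 to 16,085 unadjusted). Exact zeros were common among the calls: 59.4% of the called pairs were at 0 in both replicates of a compared group, against 1.51% of all pairs. Such zeros gathered on single other ends, 33 of which were at 0 for all their pairs in a group against at most 1 in 100 shuffles. The fragment of Usp5 and Cdca3 (6:124827772-124833403) had all its 23 pairs at 0 in WT as an other end, yet scored 5 or more at 26 of 39 pairs as a bait, so the zeros may come from the upstream processing; a biological loss at some pairs stays open.

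The rise of promoter means in the mutants was weighed against a difference in score scale or depth between libraries. Of the promoters higher in Flt3-ITD HSPCs, 9.09% were also called with quantile normalization. The median difference over all promoters called higher went from 0.74 to 0.44 (a median share of 0.614 left, SD 0.0812). These promoters were chosen for large differences, so the share left cannot tell scale from a true rise. Of the promoters higher in DM HSPCs 44.4% were called both ways, with a median difference of 0.88 before and 0.74 after; they were chosen for large differences, so scale and a true rise cannot be told apart from these values. Of those lower in DM HSPCs 100% were called both ways, but quantile normalization moved them further from 0 by -0.13, so this says nothing about scale. A true gain of contacts in many promoters at once would be removed by quantile normalization too, and the files hold no depth to separate it. The pairs used were also brought in by other mutants, which can favour a rise over WT.

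The weaker erythroid contacts of DM HSPCs kept 1.01 of their difference from other promoters after quantile normalization, but this moves all promoters nearly alike and so says nothing about an uneven score scale, which stays open. With any single chromosome left out, the globin loci included, at least 0.886 of the difference was left, which argues against a single locus. Fewer red cell precursors in the lineage-negative fraction of DM marrow may underlie the list as well as a change within cells, since both the mix of cells and their genotype differ between the groups, and this was not tested.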

How the results depend on the processing

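The alternatives with pairs brought in by other groups, other minimums of pairs, other transformations, pairs with no exact 0, and all results per promoter were chosen after seeing the data; the other settings were planned. Larger bins, turned signs and the compartment thresholds could not apply to scores of pairs and were not run. Values follow the order Npm1c, Flt3-ITD and DM against WT, DM against Npm1c, DM against Flt3-ITD, interaction and neutrophils against WT HSPCs, and omit results within 1.5 times the main count. Counts at an unadjusted p under 0.05 (limma) stand in brackets beside 0. Where no reason is given, the cause was not tested. No named pair reversed its direction under the alternatives checked for each, and neither did any of 60 named promoter results between HSPC groups. The named promoters of the interaction and the asinh and untransformed scores were not checked in this way. For the genes fixed beforehand reversals were not recorded. With quantile normalization 114 named pairs stayed on their side of the threshold and 16 lost it, and with trend and robust 6 stayed and 124 lost it. All 60 named promoter results tested with at least 1 and with at least 3 pairs per promoter lost their call, and 54 of 60 with at least 5. Depth is unknown, so its limits cannot be given. In fits that leave 1 library in a group, that library is assumed to vary like the other groups.

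Pairs, Benjamini-Hochberg at 0.10: 549, 1,059, 2,509, 1,631, 689, 970 and 188. Trend and robust: 0 (10,705), 1, 1, 1, 2, 2 and 0 (2,734). Mean per promoter over all listed pairs: 32, 280, 88 (DM against Flt3-ITD), 212 and 124. Only the groups compared: 0 (8,788) for Npm1c and 0 (15,491) for DM against WT and 0 (15,219) for DM against Npm1c, with fewer samples. Pairs brought in by other groups: 0 (5,900), 12, 1, 1 and 8; with only the groups compared 0 (3,500), 0 (5,240), 0 (5,555), 0 (4,815) and 0 (3,904); with quantile normalization 0 (3,925), 4, 1, 1 and 4. Pairs with no exact 0: 0 (9,890), 0 (11,150), 0 (16,085), 0 (14,477), 0 (9,280), 0 (11,253) and 0 (2,836). Untransformed scores: 4, 4, 2, 5, 10, 0 (13,777) and 0 (2,480). Median centred and SD scaled: 310 for the interaction and 5 for neutrophils. Quantile normalization: 0 (2,013) for neutrophils. Pairs at 5 in both cell types: 0 (1,004) for neutrophils; all 10 libraries in the fit: 432. Each library left out: 0 to 281, 0 to 600, 0 to 536, 0 to 587, 0 to 477, 0 to 73 and 0 to 623.

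Promoters, Benjamini-Hochberg at 0.10: 346 (Flt3-ITD against WT), 208, 21, 181 and 357. All listed pairs: 7, 471, 647, 314, 480 and 124 (neutrophils), with selection by the groups compared. At least 1 pair per promoter: 0 (637), 1, 0 (1,177), 1 (DM against Flt3-ITD) and 3 (neutrophils); at least 3 pairs: 0 (371), 0 (1,022), 0 (1,002), 0 (728) and 29; at least 5 pairs: 0 (235), 38, 1, 14 (DM against Flt3-ITD) and 342 (interaction). Trend and robust: 6, 250, 15 (DM against Npm1c) and 9 (neutrophils). Median centred and SD scaled: 0 (102), 15, 49, 7 and 14. Quantile normalization: 0 (100), 17, 11 (DM against Npm1c) and 10 (DM against Flt3-ITD), so that Flt3-ITD against WT fell from 143. Pairs with no exact 0: 0 (95), 32 (DM against Npm1c) and 132 (interaction). Untransformed scores: 0 (127), 223, 42 and 1 (DM against Npm1c). All libraries in the fit: 15 for DM against Npm1c and 3 for neutrophils. Baits with a protein-coding gene end: 5 for neutrophils. Each library left out: 1 to 4, 7 to 641, 0 to 241, 0 to 138, 0 to 71, 17 to 386 and 3 to 15.

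Over single pairs the replicate numbers showed little pairing of the samples: the correlation of replicate differences between groups was -0.0124 to 0.0613. Noise in single pairs can hide a shared batch, so pairing by replicate number is not excluded. With the replicate number as a block, limma called 287 pairs in DM against WT and 6 in the interaction, and 0 (441), 158, 0 (297) and 0 (31) promoters in Flt3-ITD against WT, DM against WT, DM against Flt3-ITD and neutrophils. With the block and quantile normalization it called 0 (73), 32, 21, 45 (DM against Flt3-ITD) and 0 (28) promoters.

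Pairs gained and lost numbered 2,848, 3,737, 5,048, 4,955 and 3,571 at 6 or more against under 4, and 4,970, 5,984, 6,537, 5,897 and 4,207 among pairs brought in by other groups, with fewer pairs counted. The mean Pearson correlation over pairs at 5 or more in all 4 groups was 0.594 within and 0.536 between groups. Fry called 5 lists and camera with an estimated correlation 0. The erythroid list (DM against WT, DM against Npm1c) and the macrophage and dendritic list (DM against Npm1c) had an adjusted p of 0.0622 with fry, which tests for any change and not against other promoters, and 0.924 with an estimated correlation. For pairs brought in by other groups, with only the groups compared in the fit, camera gave the macrophage and dendritic list an adjusted p of 0.0725. With each library left out the adjusted p was 0.000721 to 0.00874 and 0.00564 to 0.0431 for the erythroid and 0.00582 to 0.0431 for the macrophage and dendritic list. Towards neutrophils, Flt3-ITD HSPCs moved by 0.22 for differences of at least 0.4 and 0.0735 with quantile normalization, and DM HSPCs by 0.27, 0.14 and, for pairs brought in by the other mutants, 0.14. Regions of at least 2 called pairs numbered 1, 6, 7, 6, 2, 6 and 0. The share of pairs at 5 or more differed from WT by 1.63 to 11.3 (Npm1c), 10.7 to 17.1 (Flt3-ITD) and 7.86 to 14.3 (DM) with each library left out.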

Other observations

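All tests in this part were chosen only after the result was seen. Of the promoters that carry many contacts in neutrophils, Parp8, Thbd, Sstr4, Cxcr4, Klhl2 (2 pairs in WT and 7 in DM HSPCs) and B4galt6 (0 and 5) carried more contacts in DM than in WT HSPCs, and Dock5 (4 pairs in WT and 2 in DM HSPCs), Ptpre (20 and 20), Rwdd2b (10 and 4), Retnlg (0 and 0) and Selp (0 and 0 on one bait, 0 and 3 on the other) did not, or barely. Flt3-ITD HSPCs also had more than WT HSPCs at Parp8 (24), Thbd (34), Sstr4 (30), Cxcr4 (22), Klhl2 (10), B4galt6 (1), Ptpre (34), Dock5 (7) and Rwdd2b (13). Npm1c HSPCs had more at Parp8 (4), Thbd (17), Sstr4 (9), Cxcr4 (14), Klhl2 (7), Ptpre (36) and Dock5 (6). They had as many as WT HSPCs at B4galt6 (0) and Rwdd2b (10). Retnlg and Selp had 0 in both single mutants. DM HSPCs had more pairs at 5 or more over the whole list too, 43,228 against 30,921 in WT HSPCs. The promoter of Cebpa, the granulocyte master factor, had 6 pairs at 5 or more in DM HSPCs, 0 in WT HSPCs and 1 in neutrophils. Ferroportin (Slc40a1) went the other way: it was lower in DM HSPCs and higher in neutrophils than in WT HSPCs. Mmp8, a collagenase of neutrophil granules, had 2 pairs at 5 or more on one bait in WT HSPCs, 11 in DM HSPCs and 9 in neutrophils, and 4, 16 and 15 on the other.

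The hypothesis that DM HSPCs carry contacts of the neutrophil state was tested at promoters with at least 10 neutrophil pairs and many more than in a WT HSPC library, measured in the other WT library. Their excess over other promoters was 0.20 in DM HSPCs (0.14 to 0.26 over libraries and WT splits), 0.11 in Flt3-ITD (-0.01 to 0.24) and -0.03 in Npm1c HSPCs (-0.14 to 0.10). The Flt3-ITD excess was 0.18 and 0.24 against WT replicate 2 and -0.01 and 0.02 against WT replicate 1. The smaller of the mean excesses of the DM libraries was 0.193, just under the bound of 0.2, so contacts of the neutrophil state and their absence cannot be told apart by this test. After quantile normalization the DM excess was 1.01 times as large, which decides nothing, since the correction moves all promoters nearly alike. A larger share of granulocyte precursors in the lineage-negative fraction could give the same values and was not tested.

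The Mad2l1 promoter contacted several fragments of chromosome 11: the strongest pair in 11:46596398-46610014 scored 16.4 (SD 5.18) in Npm1c HSPCs and 0 in the other HSPC groups, and with 11:46694130-46697369 it was 17.2 (SD 10.1) in Npm1c and 7.87 (SD 5.39) in Flt3-ITD HSPCs and 0 in WT and DM HSPCs. Elane, a protease of early granulocytes, had 15 pairs at 5 or more in WT, 4 in Npm1c, 14 in Flt3-ITD and 11 in DM HSPCs and 5 in neutrophils on one bait, and 1, 5, 2, 4 and 0 on the other.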
